A study of Saccharomyces cerevisiae and Mus musculus with 117 samples.

How the data were processed

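The yeast FPKM table was deposited by the authors with 8 columns, wild type and 7 anchor-away strains, and the deposited column names describe merged replicates, so each column was read as the authors' pooled value with no SD and no n. Per the submitters' processing notes, TopHat2 2.0.8, Cuffdiff 2.0.2, Bowtie 0.12.9 and TopHat (no version given) were used, with sacCer3 for yeast and mm9 for mouse, and the notes do not say which step used which tool. The log2 ratios along genes were made by the authors, as the deposited file names say, from a strain or knockdown over its control. Their bins hold 0, or in chromatin RNA a constant per file, where nothing was measured, and such bins were treated as empty. The labels do not say whether a ratio file without a replicate number pools replicates, so each was read as a single value per gene. The telomere files are deposited log2 ratios of immunoprecipitate over input, and list only positions the authors found enriched, on a grid read as 50 bp wide, 400 positions per end and 32 ends. The mouse RPKM column was deposited by the authors for mock cells only, so mouse gene expression under knockdown is not analysed here. The lists of bound genes and the metagene clusters are the authors' own deposited lists of other values, made from the same series, the clusters by k-means in Cluster 3.0 per the accompanying deposited note.

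Per the labels, yeast libraries were stranded and poly(A) selected, rapamycin was given at 8 µg/ml for 24 hours to the 7 anchor-away strains and their wild type, the labels of the NHP6A and NHP6B deletion name no rapamycin, and mouse cells were collected 72 hours after transfection. Samples with labels and no processed file given here (RNA after anchor-away of RAP1, ChIP after anchor-away of TBP, Med1 ChIP, yeast H3K79me3 and mouse ChIP of the 3 factors) are not analysed here. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. The files used here hold no counts, so the depth is unknown and no count model was fitted.

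For expression, log2(FPKM + 1) of each strain minus that of wild type was taken for the 6620 of 6660 genes with at least 1 FPKM in any column, and a log2 change of at least 1 either way was counted. The design had planned limma where each replicate had a column, and since each strain had 1 column no test was run. Of the 6660 genes, 5986 matched a locus tag of the R64 yeast reference, 5255 had a name there, and 89.6% had the same start and end, and names came from that match. Distances to telomeres came from the authors' column, and grouping genes by that distance was chosen after the table had been seen. Gene lists, 17 for yeast, were fixed from the labels alone. The median of each was placed among 10000 random lists of the same size drawn from 20 bins of expression (1000 lists for bound mouse transcripts). For FPKM changes the bins used the mean of log2(FPKM + 1) in wild type and in the strain, so the matching holds the strain's own level. For yeast ratios the bins used wild-type FPKM, and for mouse ratios mock RPKM. The 15 mouse lists use symbols, and the pairing of RefSeq identifiers with symbols is not given in the sources used here, so they were not applied.

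For ratio files, each gene's value was the mean over its filled body bins (15 bins in yeast, 60 in mouse), with values also over the first 500 bp and the 10 bins of 100 bp upstream. Yeast files held 5228 genes, or 5231 for Nc2b replicate 2 and for the NHP6A and NHP6B deletion. Mouse files held 26228 transcripts, and of transcripts with the same coordinates 1 was kept, which left 23157. As another scaling, the ratios of a strain were shifted by the median difference between its sense ratio and its FPKM change, which was 0.93 for Mot1, 1.15 for Nc2a, 0.80 for Nc2b, 0.65 for Ino80, 1.58 for Mot1 with Ino80, 1.22 for Nc2a with Ino80 and 1.27 for Nc2b with Ino80. For Nc2b alone the difference was taken from replicate 1 and applied to both replicates and their mean. A shift by log2 of the wild-type total over the strain total, from FPKM times gene length, was also run, chosen after the data had been seen. Where 2 replicate ratios existed (Nc2b, chromatin RNA and Pol II of Mot1 with Ino80), limma tested per gene whether their mean differs from 0, two-sided, with Benjamini-Hochberg adjustment at 0.05 over all genes tested and, for fixed lists, over the list alone. Overlap of called and bound genes was tested by Fisher's exact test, two-sided.

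For telomeric ChIP, the number of listed positions and their mean log2 were averaged per genotype within each protein, and the mean difference over 3 proteins was tested by exact permutation of genotype within protein, two-sided. Per the labels, Arp5 and Mot1 were precipitated from the same strains with the same inputs, so the test was also run with the labels of both permuted together, an alternative chosen after the data had been seen. The contrast of positions within 2 kb against those at 10 to 20 kb used the test with both permuted together and was chosen after the profiles had been seen. Shares of genes are given with 95% Clopper-Pearson intervals where a report sentence prints them, and these cover counting error only.

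Named genes were chosen by a fixed rule. It took the targeted genes, then the 10 highest and 10 lowest named genes past the threshold (an FPKM of at least 5 in the higher condition, most bins filled in ratio files, or an adjusted p under 0.05 with the same sign in both replicates), then the 2 members of each list with the largest change in the list's direction. Unnamed genes were passed over, 1 among the highest and 7 among the lowest for Mot1 with Ino80. Alternatives covered a pseudocount of 0.1, an FPKM minimum of 5, centring on the median gene, genes bound by all 3 factors, the first 500 bp, medians in place of means over bins, genes with most of their bins filled (at least 50%), each replicate left out, and 10 kb in place of 20 kb, while 30 kb was not run since the files end at 20 kb. The tests were checked on simulated data with changes of known size, and with log2 changes of 4 they recovered 100% in Nc2b sense RNA, 95.5% in Nc2b antisense RNA, 100% in Pol II and 0% in chromatin RNA over all transcripts. The simulation shuffled replicate noise among genes with about as many filled bins. Each gene's own spread was not kept, so recovery in the real data may differ. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 with random seed 7.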

Results

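The series measured RNA and chromatin in budding yeast and in mouse embryonic stem cells after loss of Mot1, Ino80 or the subunits of NC2. Mot1 and NC2 act on the TATA-binding protein at promoters, and Ino80 is the ATPase of a complex that remodels nucleosomes. The labels described 117 samples, 73 from yeast and 44 from mouse, in 66 groups, of which 51 had 2 samples and 15 had 1 sample. In yeast, 7 anchor-away strains, in which rapamycin draws the tagged protein out of the nucleus, had stranded mRNA sequencing beside a wild type given the same drug. Yeast also had a deletion of NHP6A and NHP6B, and chromatin immunoprecipitation (ChIP) of Arp5, Mot1 and Nc2b with and without SIR3. Mouse cells treated with small interfering RNAs had sequencing of RNA, of chromatin-bound RNA, of RNA polymerase II (Pol II) ChIP and of H3K79me3 ChIP. The deposited tables held FPKM, RPKM or log2 ratios and no counts, so the sequencing depth behind each value is unknown.

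The comparison of yeast gene expression addressed which mRNAs differ once Mot1, Ino80 or NC2 leaves the nucleus, and the strain that lacked both Mot1 and Ino80 had far higher stress-response mRNAs. SIP18, a desiccation-response gene, went from 13.4 FPKM in wild type to 672 FPKM, a log2 change of 5.55. HSP12, which encodes a small membrane heat-shock protein, went from 99.3 to 4091 FPKM, a log2 change of 5.35. The chaperone gene SSA4 had a log2 change of 4.61, and the chaperone gene HSP26 had one of 4.55. NQM1, the paralogue of a pentose phosphate enzyme gene, had a log2 change of 5.32, and SPG4, named for stationary phase, had one of 4.98. NCE103 (carbonic anhydrase), PDC6 (a minor pyruvate decarboxylase), SRX1 (sulfiredoxin) and DPA10 were also among the 10 highest named genes, with log2 changes of 4.84, 4.77, 4.69 and 5.22.

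The 10 lowest named genes in the same strain follow, of which the phosphate genes belong to a fixed list weighed below. SEC53, which encodes a phosphomannomutase for protein glycosylation, went from 2711 to 86.2 FPKM, a log2 change of −4.96. The acid phosphatase genes PHO12 and PHO11 had log2 changes of −4.45 and −4.30, and SPL2, which restrains low-affinity phosphate uptake, had one of −4.38. The ribosomal protein gene RPL23A went from 10377 to 592 FPKM, a log2 change of −4.13. HXT4 (a hexose transporter), MEP2 (an ammonium permease), DUG1 (a dipeptidase), PNS1 and INA1 had log2 changes of −4.10, −4.02, −4.08, −4.67 and −4.31. Of the targeted genes and their partners, MOT1 mRNA had a log2 change of 2.67, INO80 mRNA 0.80, BUR6 mRNA 2.43 and NCB2 mRNA −0.19. Anchor-away moves protein and not RNA, so these mRNA levels do not check the labels.

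Across the 6620 genes with at least 1 FPKM in any column, 1391 (21.01%) were higher and 1416 (21.4%) lower by a log2 change of at least 1 in the strain that lacked Mot1 and Ino80. In the ratio files of the same strain, scaled differently, 3526 genes had a sense log2 of 1 or more and 122 had one of −1 or less. All log2 changes of FPKM were taken after adding 1, which understates the change of low genes. The table had 1 column per strain, which the deposited column names describe as merged replicates, so no FPKM difference has a replicate check. The median gene of this strain had a log2 change of 0.15. Among the genes that were higher, 90 were listed at 0 in either column. As a scale for these values, the SD between the sense ratios of both Nc2b replicates had a median of 0.237 over genes.

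Lists of genes fixed before the data were examined showed which functions were high and which were low in the strain that lacked Mot1 and Ino80. All 137 ribosomal protein genes were lower by at least 1, with a median of −2.91, and RPL23A and RPL20A (−3.98) led them. In the ratio files their sense median was −0.77, with 50 of 136 at −1 or less. Random lists matched on expression were low too, and none of 10000 had a median as low. Glycolysis genes had a median of −2.40, with 14 lower, 1 higher and 2 between (ENO2 −3.78, ADH1 −3.54), at percentile 21.2 of random lists of equally abundant genes. Phosphate (PHO) genes had a median of −2.27, with 11 lower and 6 between and none of the random lists as low. Heat-shock and chaperone genes had a median of 1.70, with 13 higher, 1 lower and 7 between, above all random lists. Environmental stress genes had a median of 0.89, also above all random lists, with 14 higher, 5 lower and 11 between (GND2 4.11, GRE1 3.85). Mating and pheromone genes had a median of 0.78 at percentile 99.5, with 11 higher, 4 lower and 14 between (MFA1 4.15, MFA2 3.18). Subtelomeric gene families had a median of 1.14 at percentile 100, with 42 higher, 8 lower and 32 between (THI13 3.49, HXT9 3.18). Only 33 of those 82 members were in the ratio files, where their sense median was 1.46 as deposited and −0.12 once shifted to the FPKM scaling, and near-identical copies within these families can share reads.

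For 6 lists the direction depended on the scaling. The signs given here do not tell whether a list stood out from random lists matched on expression, which the figure marks by filled points. By FPKM, inositol and phospholipid genes had a median of −0.89 with 2 higher, 8 lower and 7 between (CPT1 −2.55, EPT1 −1.83), against 0.69 in the ratio files. Histone genes had a median of −1.38 by FPKM with 7 lower and 3 between (HTB2 −2.09, HTA2 −2.06), against 0.43 in the ratio files. Respiration and alternative carbon genes had a median of −0.47 with 6 higher, 8 lower and 15 between (HXT6 −3.45, HXT7 −3.43), against 1.16 in the ratio files. Nitrogen catabolite genes had a median of −0.44 with 7 higher, 8 lower and 6 between (MEP2, MEP1 −3.35), against 1.07 in the ratio files. Amino acid synthesis (Gcn4) genes had a median of −0.04 with 7 higher, 7 lower and 13 between (HIS1 −2.39, ILV3 −2.20), against 1.47 in the ratio files. Ribosome biogenesis genes had a median of −0.02 with 6 higher, 9 lower and 24 between (NOP1 −2.75, NOP10 −2.45), against 1.87 in the ratio files. Galactose genes, above 0 under each scaling as were the meiosis and MINC lists, had a median of 0.75 with 3 higher, 1 lower and 4 between (GAL7 4.07, GCY1 3.13). Meiosis and sporulation genes had a median of 0.59 with 12 higher, 2 lower and 21 between (SPS1 2.86, SPO21 2.54). The DAN, TIR and anaerobic genes had a median of 0.15 with 2 higher, 1 lower and 9 between (TIR2 2.13, ANB1 1.49), and its sign was not stable, since centring on the median gene brought it to zero and the shifted ratios gave −0.18. The MINC and TBP-regulator genes had a median of 0.23 with 8 higher, 2 lower and 15 between.

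**Figure D1:**
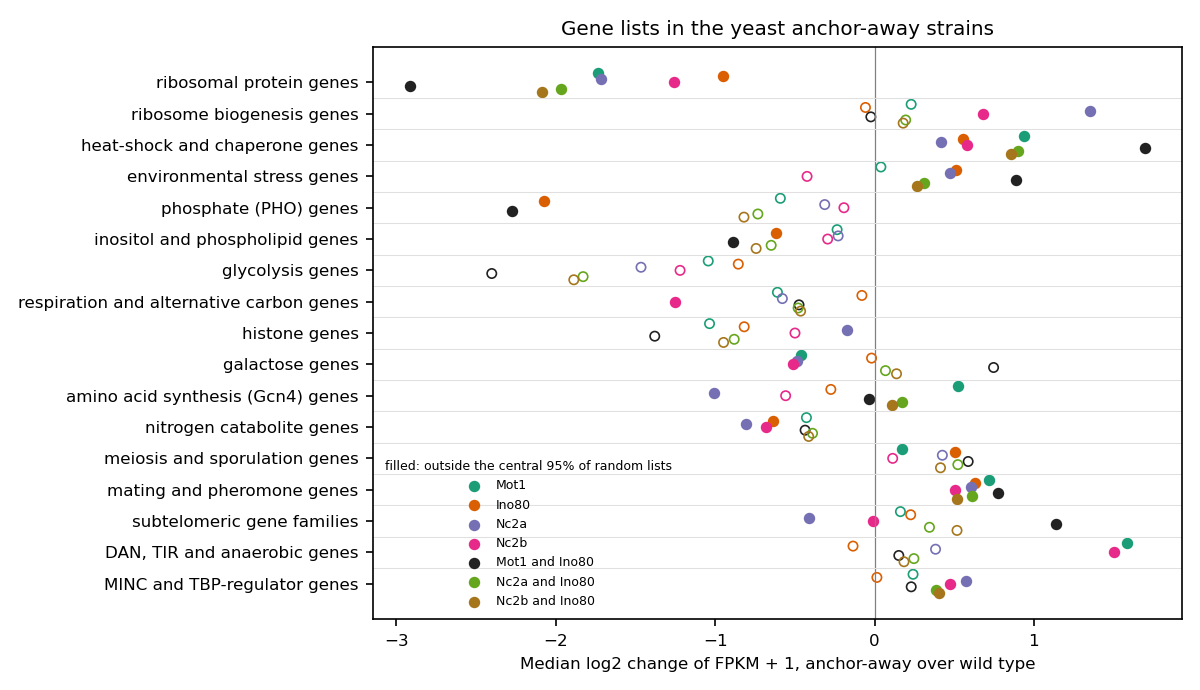
Median log2 change of FPKM + 1 against wild type (x axis) for each of 17 gene lists (y axis) in 7 anchor-away strains, with filled points outside the central 95% of random lists matched on expression. In the strain that lacked Mot1 and Ino80, ribosomal protein genes lie lowest, at −2.91, and on the ratio files' scaling the points of the inositol, histone, respiration, nitrogen, Gcn4 and ribosome biogenesis lists of that strain move from below to above 0.

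By FPKM, genes near chromosome ends were higher in the strain that lacked Mot1 and Ino80, and in the ratio files they were close to other genes. Of 161 genes within 10 kb of a telomere, 73 were higher (45.3%, Clopper-Pearson interval 37.5 to 53.4%) and 13 lower, with a median log2 change of 0.85. At 10 to 20 kb, 58 of 142 genes were higher (40.8%, interval 32.7 to 49.4%) and 23 lower, with a median of 0.67. The share that was higher was 24.7% at 20 to 40 kb and 19.7% among the 6018 genes farther in. The medians within 10 kb and at 10 to 20 kb lay at percentiles 100 and 99.8 of random lists matched on expression. The ratio files held 117 of the genes within 20 kb, with a sense median of 1.77 at percentile 24.6 of matched lists. The intervals treat genes as independent, which neighbouring members of repeated families are not.

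Removal of Mot1 alone, asking what the TBP-displacing ATPase contributes, left the hypoxic, heat-shock and mating lists high, with respiratory-chain genes among the lowest. HSP26 had a log2 change of 5.64, NCA3 4.51, DDR48 4.13 and the flocculin gene FLO11 3.93. The hypoxic genes ANB1, TIR1 and DAN1 had log2 changes of 3.60, 3.58 and 2.95, and the DAN, TIR and anaerobic list had a median of 1.58 with 7 higher and 2 lower, above all random lists. ARG1, an arginine synthesis gene, went from 53.2 to 525 FPKM, a log2 change of 3.28, and ARG3 had one of 2.62. Gcn4 genes had a median of 0.52 with 6 higher, 3 lower and 18 between. Heat-shock and chaperone genes had a median of 0.94 with 9 higher, 0 lower and 12 between, above all random lists, and mating and pheromone genes had one of 0.72 with 10 higher, 0 lower and 19 between, at percentile 99.98. COX26, COX7 and QCR10 of the respiratory chain were among the 10 lowest named genes, at log2 changes of −3.73, −2.91 and −2.72. The others were PAD1 (−3.10), MIN3 (−3.07), TPO4 (−2.92), UTR4 (−2.88), FMP49 (−2.72), RPL23A (−2.60) and PUT4 (−2.57). Respiration genes had a median of −0.61 (CYC1 −2.53, COX5A −2.34) with 2 higher, 10 lower and 17 between, at percentile 14.4 of random lists, against 0.36 in the ratio files. Of the ribosomal protein genes, 136 were lower by at least 1 by FPKM, and 7 were at −1 or less in the ratio files. In all, 724 genes were higher and 977 lower by FPKM, while in the ratio files 2492 had a sense log2 of 1 or more and 44 one of −1 or less.

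Removal of either NC2 subunit, which together form a histone-fold repressor of TBP, raised the question of whether the subunits affect the same genes. In the Nc2a strain FLO11 went from 4.34 to 1415 FPKM, a log2 change of 8.05, followed by NCA3 (4.30), YGP1 (4.29), TIR1 (4.19), DDR48 (4.11) and RRP17 (4.00). Ribosome biogenesis genes had a median of 1.35 there, with 22 higher and 3 lower, above all random lists (NOP16 2.85, RRP12 2.55). COX26 (−3.70), ADE17 (−3.39), CAM1 (−3.22), PAD1 (−2.92) and ILV6 (−2.89) were lowest in the Nc2a strain. Environmental stress genes had a Nc2a median of 0.48, with 9 higher, 2 lower and 19 between, above all random lists. The Nc2a Gcn4 median was −1.004 by FPKM (HIS4 −2.37, HIS1 −2.35) and 0.17 in the ratio files. The Nc2a subtelomeric median was −0.41 by FPKM and 0.54 in the ratio files.

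In the Nc2b strain TIR1 went from 23.8 to 1382 FPKM, a log2 change of 5.80, followed by FLO11 (5.53), ANB1 (4.81), DAN1 (4.80) and TIR4 (3.33). The DAN, TIR and anaerobic genes had a Nc2b median of 1.504, with 7 higher and 2 lower. Cytochrome genes were lowest, with CYC1 going from 1573 to 98.0 FPKM, a log2 change of −3.99, beside COX26 (−4.94), QCR10 (−4.04), COX5A (−2.995) and COX4 (−2.99). Respiration genes had a Nc2b median of −1.25, with 16 of 29 lower and 0 higher, below all random lists. Ribosome biogenesis genes had a Nc2b median of 0.68, with 14 higher and 1 lower. Environmental stress genes had a Nc2b median of −0.42 by FPKM, with 1 higher, 8 lower and 21 between, at percentile 7.35 of random lists, and a sense median of 0.29 in the ratio files. Ribosomal protein genes lower by at least 1 numbered 124 in the Nc2a strain and 103 in the Nc2b strain by FPKM, and 3 and 1 of 136 were at −1 or less in the ratio files. The counts past the threshold were 1314 higher and 1430 lower for Nc2a, and 716 higher and 1010 lower for Nc2b, by FPKM and with no replicate check on either. In the ratio files 2762 genes had a sense log2 of 1 or more and 51 one of −1 or less for Nc2a, and 1930 and 65 for the mean of the Nc2b replicates.

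Removal of Ino80 alone, asking what the remodeller contributes, left phosphate genes low and environmental stress genes high. PHO12, an acid phosphatase gene, went from 568 to 10.54 FPKM, a log2 change of −5.62, and PHO5 went from 862 to 57.6 FPKM, a log2 change of −3.88. PHO11 (−5.54), SPL2 (−5.41), PHO89 (−4.32), PHO84 (−3.27) and VTC1 (−3.17) belong to the same phosphate response, and MPC3 (−3.32) and HXT2 (−3.06) carry pyruvate and hexoses. The phosphate list had a median of −2.08, with 14 lower and 3 between, below all random lists. DPA10 (5.33), SIP18 (4.90), HSP12 (4.69), GRE1 (3.81) and NQM1 (3.31) were highest, with the cell-wall mannoprotein genes for iron FIT2 (3.31) and FIT1 (3.25) and the agglutinin gene AGA2 (3.24). Environmental stress genes had an Ino80 median of 0.51, with 11 higher, 3 lower and 16 between, above all random lists. Inositol and phospholipid genes had an Ino80 median of −0.62 by FPKM (OPI3 −1.49, CPT1 −1.43) and 0.09 in the ratio files. Nitrogen catabolite genes had an Ino80 median of −0.63 by FPKM and 0.11 in the ratio files. Meiosis genes had a median of 0.50 with 10 higher and 0 lower, and 55 ribosomal protein genes were lower by at least 1 by FPKM, against 0 at −1 or less in the ratio files. In all, 406 genes were higher and 434 lower by FPKM, while 1266 and 34 reached a sense log2 of 1 and −1 in the ratio files.

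Strains that lacked Ino80 with either NC2 subunit, asking how the factors combine, had heat-shock genes high and ribosomal protein genes low. In the strain without Nc2a and Ino80, HSP12 (4.93), NQM1 (4.85), DPA10 (4.43) and the a-factor gene MFA1 (4.14) were highest, and MPC3 (−4.37), COX26 (−4.22) and PHO11 (−4.00) were among the lowest. In the strain without Nc2b and Ino80, the same 4 genes had log2 changes of 4.80, 4.57, 4.71 and 4.21, while MPC3 (−4.85), COX26 (−4.14) and PNS1 (−3.83) were among the lowest. Heat-shock and chaperone genes had medians of 0.90 and 0.86, above all random lists, with 9 and 10 higher and 1 lower in each. Phosphate genes had medians of −0.73 and −0.82 by FPKM, with 0 higher, 8 lower and 9 between in each, at percentiles 19.1 and 13.5 of random lists, and sense medians of 0.49 and 0.46 in the ratio files. Environmental stress genes had medians of 0.31 and 0.27, above the central 95% of random lists, with 10 higher, 6 lower and 14 between, and 10 higher, 7 lower and 13 between. In both strains 135 of 137 ribosomal protein genes were lower by at least 1, with medians of −1.97 and −2.08, while in the ratio files 7 and 8 of 136 were at −1 or less, with sense medians of −0.44 and −0.47. ARG1 had log2 changes of 2.496 and 2.68. The strain without Nc2a and Ino80 had 910 genes higher and 1106 lower, and the strain without Nc2b and Ino80 had 940 higher and 1167 lower, by FPKM. In the ratio files the counts at a sense log2 of 1 or more and of −1 or less were 2986 and 40, and 3057 and 43. All strains were compared with the same wild-type column, so likeness between strains was not tested.

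The comparison of strand-specific signal in yeast addressed whether RNA from the opposite strand of genes accumulates without these factors. In the strain that lacked Mot1 and Ino80, the antisense ratio was highest at VNX1, a vacuolar exchanger gene on chromosome XIV (sacCer3 34696 to 37422), at a log2 of 7.15 with a sense log2 of −0.88. TMN2, SEC12, DAS1 and FRE3 had antisense log2 ratios of 5.18, 5.17, 5.12 and 5.04, while their sense RNA ranged up to 2.00 at SEC12 and was −0.08 at TMN2. TIM44 (4.90), NAT4 (4.90), LRO1 (4.88), PSP2 (4.85) and MNT2 (4.77) completed the highest 10. Lowest were the kinase gene RIM15 (antisense −2.04, sense 4.76), the autophagy gene ATG29 (−1.93), the polyphosphatase gene PPN1 (−1.84), RPS18A (−1.83), ESC1 (−1.67) and RPS11A (−1.65). The nearest gene on the other strand of VNX1 was KRE1, 404 bp away. Sense ratios were highest at DIA3 (6.66), NQM1 (6.64), GAL7 (6.49), SSA4 (6.42), ADH2 (5.97) and SEO1 (5.57), and lowest at PNS1 (−3.18), SEC53 (−2.41), PHO12 (−2.41), RPL23A (−2.12) and PHO89 (−2.10).

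Antisense signal in that strain was above wild type at most genes on the authors' scale, and on the FPKM scale its sign depended on how the shift was made. The median antisense log2 ratio was 1.72 as deposited, with 95.03% of 5216 genes above 0, and it was 0.14, with 55.004% above 0, once the ratios were shifted so that sense values matched the FPKM changes. Shifted by log2 of the FPKM totals instead, the antisense median was −0.17. As deposited, 3939 genes reached an antisense log2 of at least 1 and 22 reached −1 or less. The median was 1.96 over the first 500 bp and 1.98 over the 1 kb upstream. The median sense log2 ratio was 1.62 as deposited and 0.04 after the shift of 1.58. Antisense minus sense, which any common scaling leaves unchanged, had a median of 0.19, and antisense was the higher in 55.3% of genes. That difference ran from −1.04 in the class of genes with the lowest wild-type FPKM through −0.17 and 0.53 to 0.96 in the highest of 4 equal classes. The antisense ratio itself was lower at abundant genes, at 1.93, 1.91, 1.77 and 1.18 in the same order, and the classes were split by the wild-type level that is the denominator of the sense ratio.

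By gene list, heat-shock and chaperone genes had an antisense median of 2.70 in that strain (1.11 after the shift), with 19 of 21 at 1 or more and above all random lists. Ribosomal protein genes had an antisense median of 0.14 as deposited and −1.45 after the shift, below all random lists. Glycolysis genes had an antisense median of 0.28, at percentile 3.66. Genes less than 20 kb from a telomere had an antisense median of 1.92, with 90 of 112 at 1 or more, at percentile 86.5. The 1746 genes that overlap a gene on the other strand had a median of 1.70, and the 1404 genes more than 1000 bp from one had 1.80, so the median differed little with distance to a neighbour. Genes on the authors' list of loci bound by all 3 factors had an antisense median of 1.63, against 1.80 for other genes. No test was possible, since each strain but Nc2b had 1 ratio per gene and strand.

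Single removals gave lower antisense medians as deposited, and all but that of Ino80 turned negative on the FPKM scale. The antisense median was 0.51 for Mot1 (−0.42 shifted), 0.67 for Nc2a (−0.48 shifted) and 0.73 for Ino80 (0.08 shifted). Removal of Ino80 with Nc2a gave 1.104 (−0.12 shifted), and with Nc2b 1.18 (−0.09 shifted). Antisense minus sense was −0.50 for Mot1, −0.54 for Nc2a, 0.11 for Ino80, −0.12 for Nc2a with Ino80 and −0.09 for Nc2b with Ino80. The sense medians were 0.93, 1.12, 0.55, 1.21 and 1.25 in that order, and none was above 0 after the shift. Antisense ratios were highest at SNX41 (4.42), ZAP1 (4.08) and DGR2 (4.07) without Mot1, at BSP1 (4.01), DAN1 (3.99) and CEM1 (3.86) without Ino80, and at DGR2 (5.74), TMN2 (4.47) and BUD14 (4.39) without Nc2a. The antisense strand of RIM15 was low in all 3, at −3.17, −2.91 and −2.84.

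**Figure D2:**
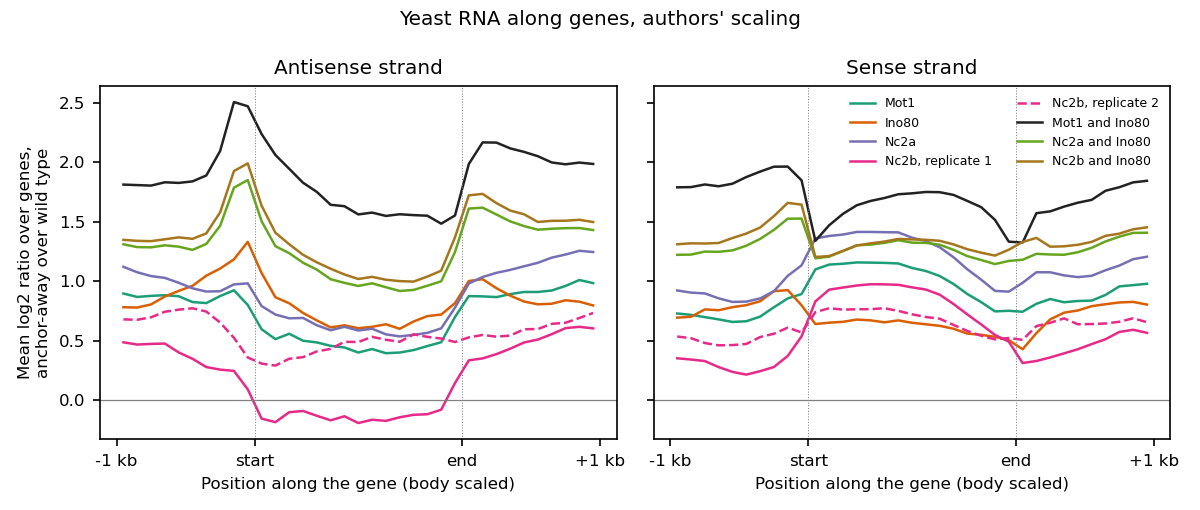
Mean log2 ratio of anchor-away over wild type (y axis) along genes from 1 kb before the start to 1 kb after the end (x axis), antisense and sense apart, with a line per strain and per Nc2b replicate. The strain that lacked Mot1 and Ino80 has the highest medians over genes, which were 1.72 antisense and 1.62 sense as deposited and become 0.14 and 0.04 on the FPKM scaling, where the antisense medians of the other strains, except Ino80 alone, turn negative.

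The Nc2b anchor-away had ratio files for 2 replicates, each with its own wild type, and so allowed a test of which strands changed. Sense RNA rose most at the hypoxic cell-wall genes DAN1 (log2 6.05, SE 0.46, limma adjusted p 8.36e-05) and TIR1 (log2 5.31, SE 0.26, limma adjusted p 4.29e-05). MOT1 (4.38), ANB1 (3.78), the glucan synthase gene GSC2 (3.66), PEX19 (3.62), HES1 (3.60) and NCA3 (3.35) followed. Sense RNA fell most at CIR2 (log2 −3.48), the proline permease gene PUT4 (−2.40), CYC1 (−2.15, limma adjusted p 0.000132), SNO3 (−2.13), QCR10 (−2.09), NDE1 (−1.98) and HO (−1.97). Antisense RNA, whose calls did not hold under 2 other ways of summarising bins, rose most at DGR2 (log2 4.01, SE 0.66, limma adjusted p 5.14e-05), the fatty acid activation gene FAA1 (3.80, limma adjusted p 0.000121) and CIR2 (3.45, limma adjusted p 0.000756). SSH1 (3.33), MEP3 (3.20), SLI1 (3.19) and HIS7 (3.04) followed, and antisense RNA fell most at MSG5 (−3.59, limma adjusted p 0.000388), RPL14A (−3.18), PGA3 (−2.84), TEL2 (−2.50) and RIM15 (−2.44). Of the targeted and partner genes, BUR6 and INO80 sense RNA rose by 2.11 and 1.69 and NCB2, the gene of the tagged subunit, had a log2 of −0.11 (limma adjusted p 0.703).

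By limma at an adjusted p of 0.05, 2713 of 5216 genes were higher and 177 lower in sense RNA, and 30 of 4987 were higher and 8 lower in antisense RNA, where 614 had an unadjusted p under 0.05. After centring on the median gene, which by construction puts about as many genes above 0 as below, the sense calls were 1515 higher and 1281 lower. The antisense calls were 0 and 0 with medians over bins and over the first 500 bp. At the 38 genes called in antisense RNA the median absolute log2 was 2.72 as reported, 2.77 with medians over bins and 2.64 over the first 500 bp (31 genes), with median SEs of 0.663, 0.584 and 0.716. The calls ended as limma's prior degrees of freedom went from 161 to 5.84 and 4.08, so they rest on how far limma pools the spread over genes. The median antisense ratio was −0.11 in replicate 1 and 0.45 in replicate 2, and its mean went from 0.16 as deposited to −0.64 after the shift. The sense medians were 0.77 and 0.56, and their mean went from 0.68 to −0.12. The shift came from replicate 1, whose sense median was the higher. The SD between replicate medians was 0.3997 antisense and 0.150 sense. Across genes, Spearman's rho between replicates was 0.26 antisense and 0.85 sense, with genes not independent of each other. On simulated data the antisense test recovered 2.99% of changes of log2 2 and 95.5% of those of log2 4. In data like those simulated, which did not keep each gene's own spread, most antisense changes near log2 2 would be missed.

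Among the fixed lists, 30 of 37 ribosome biogenesis genes rose in Nc2b sense RNA (31 adjusted over the list alone), 14 of 21 heat-shock and chaperone genes (15 adjusted over the list alone) and 18 of 22 mating and pheromone genes (18 adjusted over the list alone). These 3 lists kept medians above 0 after the shift, at 0.71, 0.29 and 0.12, and as deposited they lay at percentiles 100, 99.78 and 52.96 of random lists matched on expression, so the mating list did not stand out. Of 10 DAN, TIR and anaerobic genes 7 rose and 1 fell (7 and 3 adjusted over the list alone), with a median of 2.05 and a shifted median of 1.25. Meiosis genes rose at 11 of 16 and fell at 1 (11 and 1 adjusted over the list alone), while their median of 1.097 lay at percentile 0.89 of random lists matched on expression. MINC and TBP-regulator genes rose at 16 of 25 (16 adjusted over the list alone). Ribosomal protein genes fell at 12 of 136 and rose at 0 (1 and 0 adjusted over the list alone), with 124 uncalled, a median of −0.27 and a shifted median of −1.07. Respiration genes rose at 4 and fell at 7 of 24 (4 and 7 adjusted over the list alone), with a median of −0.37. Glycolysis genes rose at 3 and fell at 4 of 17 (3 and 4 adjusted over the list alone), with a median of −0.29.

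For the lists that follow, the Nc2b sense median was above 0 as deposited and below 0 after the shift, which was taken from replicate 1. Environmental stress genes rose at 9 and fell at 3 of 26 (7 and 3 adjusted over the list alone), and phosphate genes rose at 8 and fell at 2 of 17 (8 and 2 adjusted over the list alone). Inositol genes rose at 8 of 17 (8 adjusted over the list alone), galactose genes at 3 of 6 (3 adjusted over the list alone) and histone genes at 1 of 10 (0 adjusted over the list alone). Gcn4 genes rose at 7 and fell at 4 of 26 (7 and 4 adjusted over the list alone), and nitrogen catabolite genes rose at 5 and fell at 3 of 19 (5 and 2 adjusted over the list alone). Subtelomeric family genes rose at 14 and fell at 3 of 33 (14 and 3 adjusted over the list alone). In antisense RNA, limma called 2 mating genes and 1 nitrogen catabolite gene higher and 1 ribosomal protein gene lower (2, 1 and 2 adjusted over the list alone). Adjusted over the list alone, antisense RNA was also called at 2 respiration genes higher and 2 lower, 1 phosphate and 1 subtelomeric gene each way, 1 meiosis gene higher and 2 environmental stress genes lower.

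Genes bound by all 3 factors, a list the authors made from ChIP of the same study, were not over-represented among the Nc2b calls, while their sense median was high for their expression. The list held 1415 of the 2713 genes with higher sense RNA (Fisher exact two-sided p = 0.637) and 100 of the 177 with lower sense RNA (Fisher exact two-sided p = 0.285). It held 17 of the 30 genes with higher antisense RNA (Fisher exact two-sided p = 0.717) and 5 of the 8 with lower antisense RNA (Fisher exact two-sided p = 0.730). Bound genes were 52.5% of those tested in sense RNA and 52.9% in antisense RNA. Against random lists matched on expression, the Nc2b sense median of bound genes (0.659) lay at percentile 100, above the central 95% of lists (0.490 to 0.532), and the antisense median (0.0950) lay at percentile 62.8.

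Deletion of the HMGB-family genes NHP6A and NHP6B, asking whether the same transcripts accumulate, had environmental stress genes high and ribosomal protein genes low in sense RNA. NCE103 (3.23), HSP42 (2.96), the glycogen branching gene GLC3 (2.83), the trehalose gene TSL1 (2.69) and the catalase gene CTT1 (2.41) had high sense log2 ratios. FRE4 (−2.81), TIR1 (−2.38), NMD5 (−2.08), URA1 (−1.70) and FET3 (−1.38) had low ones, and TIR1 and NMD5 had antisense log2 ratios of 2.03 and 2.43. Antisense ratios were highest at SNX41 (3.14), BRR1 (3.10), COX11 (2.81), JHD1 (2.47) and HMG2 (2.38) and lowest at LIF1 (−4.40), GPD1 (−3.53), DGR2 (−2.40) and URA1 (−2.27). Environmental stress genes had a sense median of 1.43, with 9 of 13 at 1 or more, above all random lists, and heat-shock genes had one of 0.93. Ribosomal protein genes had a sense median of −0.45 and glycolysis genes one of −0.71. Antisense medians were 0.64 for genes within 20 kb of a telomere (16 of 55 at 1 or more, percentile 99.98), 0.67 for subtelomeric families (9 of 22) and 1.06 for DAN, TIR and anaerobic genes. The medians over genes were 0.19 antisense (2607 genes) and 0.14 sense (2623 genes). The labels gave 2 deletion samples in different backgrounds, W303-1A and SEY6210, and the ratios were those of SEY6210, labelled replicate 2. Only 1 ratio file existed for each strand, body bins of minus-strand genes were filled at only 2.38% (antisense) and 2.77% (sense), and no FPKM column allowed another scaling, so these values have no replicate or scaling check.

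Fewer positions within 20 kb of telomeres were listed as enriched for Arp5 (an INO80 complex subunit), Mot1 and Nc2b without Sir3, a silencing protein of telomeric chromatin. The number of positions listed as enriched, of 12800, went from 4537 ± 246 in wild type to 3380.5 ± 1085 without SIR3 for Arp5 (SD, n = 2 each). For Mot1 it went from 1888.5 ± 82.7 to 1298.5 ± 648, and for Nc2b from 2159 ± 117 to 659 ± 448 (SD, n = 2 each). The mean number in the deletion was 74.5%, 68.8% and 30.52% of that in wild type. The Mot1 files listed 840 and 1757 positions in the deletion and 1830 and 1947 in wild type, and the Arp5 files 2613 and 4148 against 4363 and 4711, so deletion replicate 1 carried most of the difference for both. Over the 3 proteins the mean difference was −1082 positions (exact permutation within proteins, two-sided p = 0.00926), and it was −617.7 without replicate 1 and −1547 without replicate 2 (exact permutation, two-sided p = 0.25 each, the smallest possible). Arp5 and Mot1 were precipitated from the same strains against the same inputs, however, and with both permuted together the exact two-sided p was 0.0556, the smallest of its 36 arrangements, so a p under 0.05 cannot be reached. The mean log2 enrichment at listed positions differed by −0.14 for Arp5, −0.03 for Mot1 and −0.06 for Nc2b, with a mean of −0.08 (exact permutation within proteins, two-sided p = 0.0648, and p = 0.111 with Arp5 and Mot1 together), so it was not shown to change.

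The share of listed positions was compared near the telomere and farther in. Within 2 kb, the share of positions listed went from 64.4 ± 1.93% to 36.9 ± 16.4% for Arp5, from 28.8 ± 5.63% to 10.0 ± 1.66% for Mot1 and from 33.5 ± 20.9% to 5.70 ± 2.98% for Nc2b (SD, n = 2 each). At 10 to 20 kb the shares went from 28.9 ± 2.77% to 24.7 ± 7.17%, from 9.97 ± 1.02% to 9.30 ± 6.09% and from 13.0 ± 0.243% to 4.98 ± 2.61% (SD, n = 2 each), and the Mot1 deletion files had 5.00% and 13.6%. The log2 of the near share over the far share differed by −0.96 (exact permutation, two-sided p = 0.0556 with Arp5 and Mot1 permuted together, the smallest p possible). Both deletion files had fewer listed positions than both wild-type files at 20 of 32 chromosome ends for Arp5, 12 for Mot1 and 26 for Nc2b, and no end had more in both. At the left end of chromosome III, Arp5 had 151 and 158 positions in wild type and 85 and 105 in the deletion, Mot1 had 162 and 151 against 35 and 63, and Nc2b had 61 and 171 against 7 and 31. For a protein alone, exact permutation of 2 files against 2 cannot reach a p of 0.05.

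**Figure D3:**
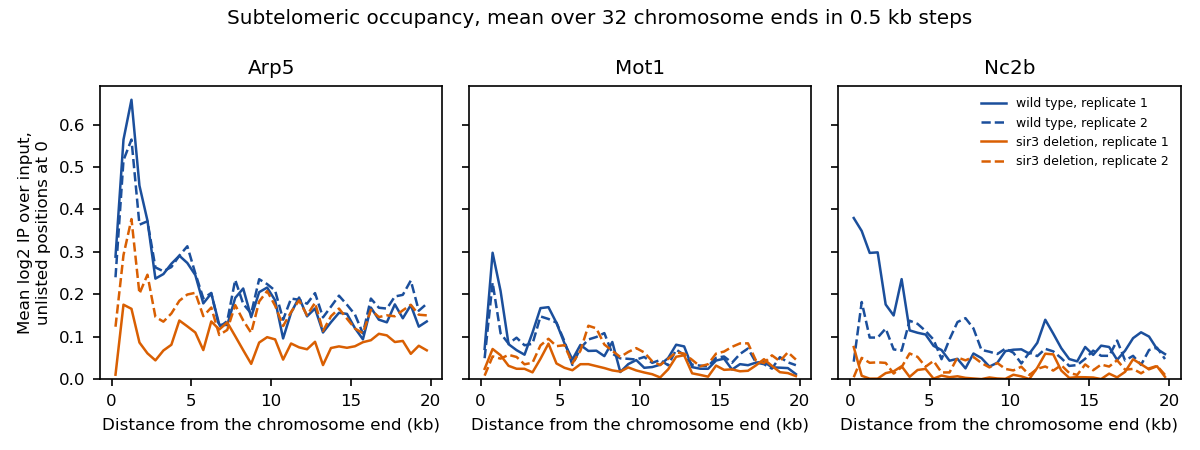
Mean log2 ratio of immunoprecipitate over input with unlisted positions at 0 (y axis) against distance from the telomere in steps of 0.5 kb over 32 chromosome ends (x axis), for Arp5, Mot1 and Nc2b with a line per replicate of wild type and sir3 deletion. The share of positions listed within 2 kb went from 64.4% to 36.9%, from 28.8% to 10.0% and from 33.5% to 5.70%, and in the step nearest the telomere a Nc2b deletion line (0.0756) lies above a wild-type line (0.0410).

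In mouse embryonic stem cells the comparison addressed whether knockdown of the same factors leaves more antisense and upstream RNA, and the differences were small beside those in yeast as deposited, although not beside the yeast antisense median of 0.14 on the FPKM scale. Double knockdown of Mot1 and Ino80 had a median antisense log2 ratio of −0.02 over transcript bodies, a sense ratio of 0.08 and an upstream antisense ratio of 0.16, with 55.8% of upstream values above 0. Knockdown of Ino80 with NC2 had −0.03, 0.05 and 0.23 for the same quantities. Per the labels, single and double knockdowns had separate mock samples, so any contrast between them is confounded with that between the mocks. The single knockdowns had lower upstream antisense medians, at −0.08 for Ino80, −0.18 for Mot1 and −0.22 for NC2. Their antisense bodies had −0.04, 0.07 and −0.03, and their sense bodies 0.02, 0.12 and 0.08. Upstream antisense minus body sense, free of common scaling, was 0.17 for Ino80 with NC2 and 0.08 for Mot1 with Ino80. For Ino80, Mot1 and NC2 alone it was −0.11, −0.28 and −0.30. The upstream sense medians were 0.17, 0.12, −0.05, 0.02 and −0.04 in the same order. Over the first 500 bp in place of the body, the sense medians of Ino80, Mot1 and NC2 were −0.0945, −0.0578 and −0.0945. Among well-filled transcripts the antisense medians of Ino80 and NC2 were 0.0769 and 0.0643, above 0. Each knockdown had 1 ratio per strand and no replicate check, while the replicate medians of chromatin RNA had SDs of 0.0445 antisense and 0.0602 sense. Transcripts were named by RefSeq identifiers without symbols, so mouse genes could not be grouped by function.

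Chromatin-bound RNA, measured to catch transcripts before they decay, had higher antisense than sense ratios after knockdown of Mot1 and Ino80 in both replicates. The antisense median over bodies was 0.17 and 0.10, and the sense median 0.02 and −0.06. Antisense upstream of the start had medians of 0.25 and 0.40, with 57.2% and 59.998% of transcripts above 0. Antisense minus sense was 0.15 and 0.21 over bodies, and upstream antisense minus body sense was 0.25 and 0.37. The upstream sense medians were themselves 0.08 and 0.20, above those of sense bodies. Bins where nothing was measured held −0.0185 in replicate 1 and 0.238 in replicate 2, and were treated as empty. Whether filled bins with few reads lean towards that constant was not tested. Fewer body bins were filled in antisense than in sense files. Such a lean would raise antisense over sense in replicate 2, so that replicate is the weaker check. Upstream antisense was higher at transcripts bound by all 3 factors than at others. The medians were 0.27 against 0.21 in replicate 1 and 0.48 against 0.16 in replicate 2. Bound transcripts were also the more expressed. Random lists matched on expression mostly had medians from 0.221 to 0.265 in replicate 1 and from 0.403 to 0.440 in replicate 2. Among those lists the bound medians lay at percentiles 97.55 and 100, so much of the gap in replicate 2 went with expression. By limma with Benjamini-Hochberg adjustment, 0 of 15309 transcripts changed in antisense RNA (1393 at an unadjusted p under 0.05) and 0 of 18489 in sense RNA (2467 at an unadjusted p under 0.05). Upstream antisense had 0 calls among 9346 by limma (1124 at an unadjusted p under 0.05). The simulated test recovered none of the changes up to log2 4 over all transcripts, so absence of calls over all transcripts sets no bound. With at least 50% of the bins filled, limma called 0 of 2402 in antisense RNA. On simulated data that fit recovered 76.1% of changes of log2 2 and 100% of those of log2 4. The simulation shuffled noise among transcripts and so did not keep each transcript's own spread. These shares therefore set no bound on what the test missed. After centring on the median transcript that antisense fit called 4 higher and 4 lower. In sense RNA with at least 50% of the bins filled, limma called 500 of 15064 higher and 615 lower, and 0 and 0 after centring. The median absolute log2 of those 1115 transcripts was 0.930 before and 0.926 after centring and their median SE 0.247 and 0.176, so the calls ended because limma's prior degrees of freedom went from infinite to 4.26 and not because the differences shrank. The largest of those sense differences were NM_019916 on chromosome 11 (mm9 33100752 to 33103588, log2 2.41, limma adjusted p 3.43e-18), NM_026916 on chromosome 5 (2.30), NM_007640 on chromosome 3 (−2.33, replicates −3.27 and −1.40) and NM_028937 on chromosome 3 (−2.31). Limma gave every transcript the same SE of 0.247 in the fit before centring. Across transcripts, which are not independent, rho between replicates was 0.12 antisense and 0.35 sense.

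**Figure D4:**
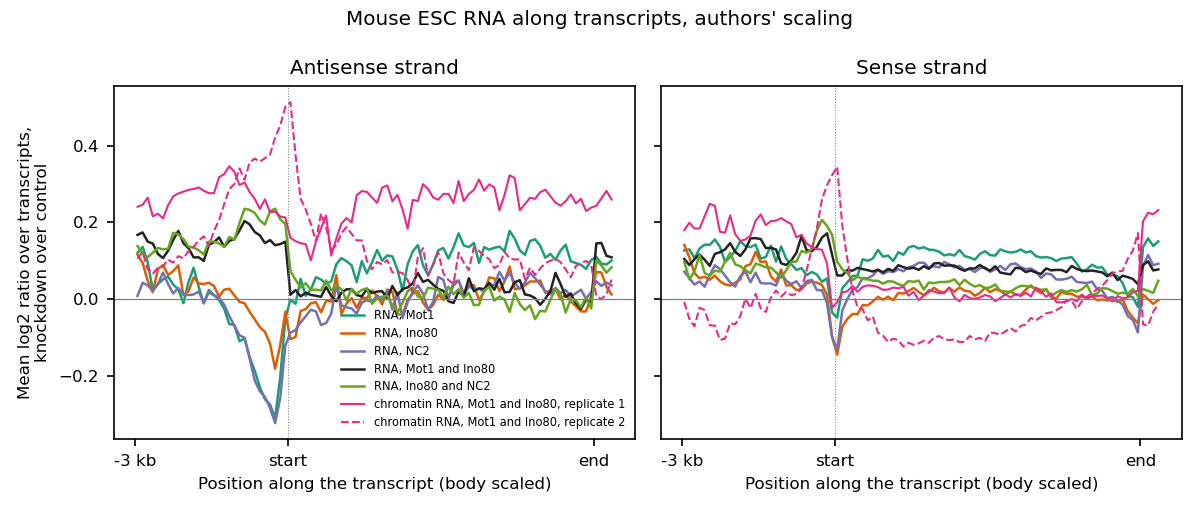
Mean log2 ratio of knockdown over control (y axis) from 3 kb before the start to the end of mouse transcripts (x axis), antisense and sense apart, for 5 RNA knockdowns and both chromatin RNA replicates of Mot1 and Ino80. Chromatin RNA had upstream antisense medians of 0.25 and 0.40, and the single knockdowns had ones of −0.08, −0.18 and −0.22.

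Pol II ChIP, asking whether polymerase follows the RNA, differed between its replicates at transcript starts and in its spread over bodies. Over bodies the median log2 ratio after knockdown of Mot1 and Ino80 was 0.04 in replicate 1 and −0.02 in replicate 2. It was 0.02 after knockdown of Ino80 and NC2. The body quartiles were −0.09 and 0.17 in replicate 1 and −0.78 and 1.04 in replicate 2, so replicate 2 varied far more. Over the first 500 bp it was 0.01 in replicate 1 and 1.08 in replicate 2, and 0.03 for Ino80 and NC2. By limma, 0 of 21114 transcripts changed over bodies (1581 at an unadjusted p under 0.05). That fit weighs both replicates alike, so the wide spread of replicate 2 limits it. The simulated test recovered 50.7% of changes of log2 2, but it did not keep each transcript's own spread, so this share sets no bound. The start-site rise in replicate 2 was lower at transcripts bound by all 3 factors (0.64) than at others (1.64). Within the mock RPKM class of 1 to 5 it was 0.67 against 2.16, and above 20 it was 0.81 against 2.28, while among transcripts listed at an RPKM of 0 it was 0.90 at 100 bound ones against −0.07 at others. Across transcripts, which are not independent, rho between the replicates was 0.30. Since 1 library decides the start-site value, no change of Pol II at starts was shown.

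H3K79me3, a histone mark of transcribed gene bodies, had log2 ratios near 0 over mouse transcript bodies and well above 0 at starts. The body medians were 0.08 for Ino80 knockdown, 0.05 for Mot1 and 0.04 for NC2, and the first 500 bp had medians of 1.14, 0.93 and 0.81, with 83.7%, 83.5% and 82.95% of transcripts above 0. Over the 1 kb upstream the medians were 0.50, 0.39 and 0.35. At bound transcripts the first 500 bp had medians of 1.75, 1.498 and 1.31, against 0.47, 0.34 and 0.29 at others. Bound transcripts were the more expressed, and the differences were 1.28, 1.16 and 1.02 in the same order. Within every class of mock RPKM they were smaller, at 1.03, 0.91 and 0.82 for 0 to 1 and 0.62, 0.65 and 0.55 above 20. Each knockdown had 1 file and no test. The denominator was taken from the deposited names, and the values alone do not tell a ratio to a control immunoprecipitate from a ratio to input. Of filled body bins, 6.89%, 8.71% and 9.59% lay within 1e-05 of 0.

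**Figure D5:**
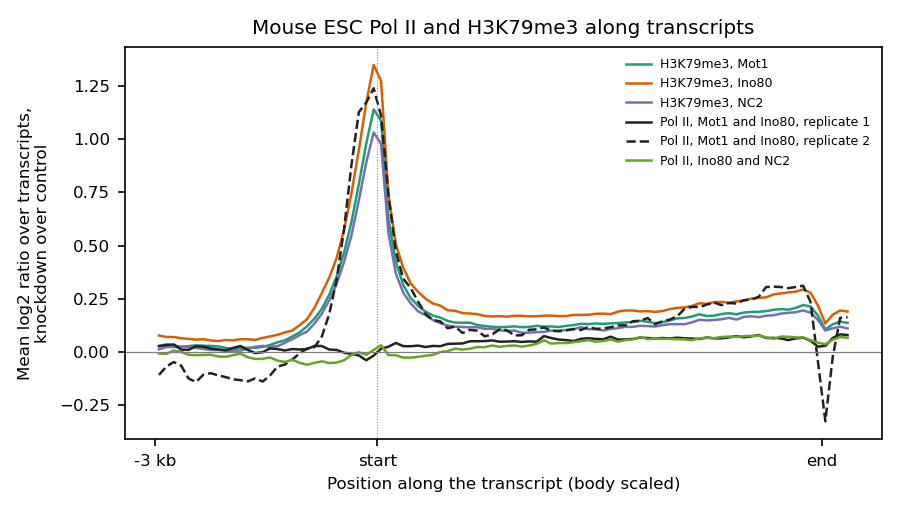
Mean log2 ratio (y axis) from 3 kb before the start to the end of mouse transcripts (x axis) for H3K79me3 after 3 knockdowns and Pol II after Mot1 with Ino80 (both replicates) and Ino80 with NC2 knockdown. The H3K79me3 lines and Pol II replicate 2 are highest in the last 100 bp before the start, at 1.35, 1.14, 1.03 and 1.24, and the medians over the first 500 bp after it were 1.14, 0.93, 0.81 and 1.08, against 0.01 in Pol II replicate 1.

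The authors' list of mouse transcripts bound by all 3 factors held 12161 transcripts, and bound transcripts were the more expressed. Their median mock RPKM was 5.90, against 0.0839 for transcripts off the list. Of the 12100 transcripts at an RPKM of at least 1 in mock cells, 8124 were bound. The authors grouped the bound transcripts by the shape of these same ratios, so values per group describe the grouping and test nothing. In their antisense grouping, 1906 transcripts formed a group with an upstream antisense median of 0.86 in RNA and 0.60 in chromatin RNA after knockdown of Mot1 and Ino80. A second group of 1182 had a body antisense median of 0.38 in RNA and 0.33 in chromatin RNA, and the remaining 9073 had −0.08 and 0.11. In the sense grouping, 2502 transcripts had a body median of 0.31 in RNA and 9659 had one of 0.05.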

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

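Every alternative fixed in advance was run except 30 kb from the telomere, and the shifts to the FPKM scaling and by the FPKM totals, the fit of well-filled centred transcripts, the mean over all telomeric positions, the permutations of Arp5 and Mot1 together and the upstream window were chosen after seeing data. Over the main results, 259 alternative values stayed the same, 50 moved, 24 reversed, 4 became stronger and 4 weaker. For gene-list medians, named genes and shares of genes above 0, 2339 stayed the same and 191 moved. Of those 2339, 472 came from centring FPKM changes on the median gene. Centring shifted them by at most 0.15, under the 0.237 that counted as a move, so they say little about stability. No paired analysis was possible for the FPKM and ratio results because they come from merged columns or ratios, and the cause of a difference was not tested unless stated. Shifting ratios to the FPKM scaling subtracts a constant by construction, and gave antisense and sense medians of −0.42 and -4.19e-05 for Mot1, 0.0823 and −0.10 for Ino80, −0.48 and −0.0317 for Nc2a, −0.64 and −0.12 for Nc2b, 0.14 and 0.04 for Mot1 with Ino80, −0.12 and −0.0088 for Nc2a with Ino80, and −0.0902 and −0.0251 for Nc2b with Ino80. Shifting by log2 of the FPKM totals gave −0.49 and −0.0759 for Mot1, 0.0645 and −0.11 for Ino80, −0.503 and −0.0577 for Nc2a, −0.642 and −0.12 for Nc2b, −0.17 and −0.27 for Mot1 with Ino80, −0.23 and −0.12 for Nc2a with Ino80, and −0.22 and −0.16 for Nc2b with Ino80. Bound genes alone had sense medians of 0.95 without Nc2a and 1.40 without Mot1 and Ino80, where the first 500 bp had 1.41. For Nc2b the limma antisense calls were 65 higher and 15 lower with well-filled genes, 0 and 0 with medians over bins, 0 and 0 over the first 500 bp, 17 and 5 among bound genes, and 25 lower after centring. The Nc2b limma sense calls were 906 higher and 30 lower over the first 500 bp, 1502 higher among bound genes, and 1515 higher and 1281 lower after centring. Medians of H3K79me3 were 2.10e-07, 3.49e-07 and 2.22e-07 (Ino80, Mot1, NC2) with medians over bins, 1.14, 0.93 and 0.81 over the first 500 bp, and 0.14 (Ino80) and 0.0880 (Mot1) at bound transcripts. For Pol II after Mot1 and Ino80 knockdown the median was 0.14 with well-filled transcripts, 0.60 over the first 500 bp and −0.0163 to 0.0391 with either replicate left out. In mouse RNA, well-filled transcripts had antisense medians of 0.0769 for Ino80, 0.14 for Mot1 and 0.0643 for NC2. Over the first 500 bp, Ino80 had −0.12 antisense and −0.0945 sense, Ino80 with NC2 had 0.0457 antisense, Mot1 had −0.0578 sense, and NC2 had −0.0908 antisense and −0.0945 sense. Chromatin RNA had antisense medians of 0.20 with well-filled transcripts and 0.31 over the first 500 bp, and a sense median of 0.18 over the first 500 bp. Its limma calls were 4 higher and 4 lower in antisense RNA with well-filled transcripts centred, 500 and 615 in sense RNA with well-filled transcripts, and 414 and 410 in sense RNA with bound ones.

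For the sir3 deletion, permuting Arp5 and Mot1 together, since they share strains and inputs, left −1082 positions at an exact permutation p = 0.0556, the smallest of its 36 arrangements, and the tests that follow permute each protein apart and share that limit. Exact permutation tests, two-sided, gave a mean log2 difference of −0.10 within 10 kb (p = 0.037) and −0.0610 over all positions (p = 0.00926). Leaving out a file at a time gave mean log2 differences from −0.11 to −0.0487, with an exact permutation p = 0.037 without the first Nc2b deletion replicate. Leaving out all files of replicate 1 or 2 gave −617.7 and −1547 positions (exact permutation, p = 0.25, the smallest possible with so few files). With the replicate number as a block, the paired exact permutation gave −0.0778 in mean log2 and −1082 positions, each at p = 0.0312, the smallest its 64 arrangements allow, and with Arp5 and Mot1 permuted together as well each was at p = 0.125, the smallest of 16. Deviations of same-numbered files correlated at 0.14, 0.25 and 0.45, and with only 2 pairs per protein the numbers were not taken to pair files. The unknown depth limits how far an unlisted position can be read as unbound.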

Other observations

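All tests in this part, except that on abundant transcripts, were chosen after the result they weigh was seen.

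Several growth transcripts made up much of the wild-type yeast total. Ribosomal protein genes held 33.2% of the summed FPKM times gene length in wild type and 16.3% without Mot1 and Ino80. The wild-type total over the strain total was 3.72 without Mot1 and Ino80, 2.65 without Nc2b and Ino80, 2.52 without Nc2a and Ino80, 2.25 without Nc2a, 2.01 without Mot1, 1.74 without Nc2b and 1.59 without Ino80. Genes within 10 kb of a telomere had a median log2 change of −0.64 without Nc2a, with 8 higher and 39 lower, and 17 higher and 11 lower without Ino80.

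The yeast ratio files lie above the FPKM changes of the same strains. The size of the gap fits a scaling by total signal, since the absolute difference between the offset and log2 of the totals had a median of 0.0758 over the 7 strains, although the strain without Mot1 and Ino80 departed by −0.31. Removing the most abundant transcripts took away a median of 74.4% of log2 of the totals, as was predicted before the test if those transcripts had lost most. That test cannot decide, since the median gene lay near 0 by FPKM in every strain, at log2 changes from −0.03 to 0.15. Much of the gap then had to lie with abundant genes, whichever transcripts changed. Antisense RNA may have risen beyond the scaling, but the shifted median of 0.14 without Mot1 and Ino80 cannot tell, since it was −0.17 when shifted by log2 of the totals and no spike-in was among the values used. Levels of antisense RNA and of abundant mRNA per cell would be needed to tell a rise of antisense RNA from a fall of abundant mRNA.

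Pol II replicate 2 has a start-site peak that replicate 1 lacks. A file holding H3K79me3 by mistake would be higher at bound transcripts, and the bound minus other difference was −0.996 over the first 500 bp. Across transcripts, which are not independent, however, its body values had a Spearman's rho of 0.80, 0.76 and 0.73 with the 3 H3K79me3 files, against 0.30 with Pol II replicate 1 and 0.27 with Pol II after Ino80 and NC2 knockdown, so this explanation stays open. A difference in immunoprecipitation efficiency as the whole cause was taken to leave bound transcripts, whose mock RPKM is higher, no lower than others. The highest difference over the 4 classes of mock RPKM above 0 was −0.92, while the 100 bound transcripts listed at an RPKM of 0 lay 0.97 above others. Comparing within classes of equal expression removes the ground of that prediction, so these values cannot decide on efficiency. A further replicate could settle whether the peak belongs to the knockdown.

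Fewer subtelomeric positions were listed without SIR3. A lower yield or depth of the deletion libraries would lower all distances alike, and although the near share was lower relative to the far share, the exact permutation test with Arp5 and Mot1 permuted together (two-sided p = 0.0556, the smallest possible) leaves it open. Fewer listed positions along the whole 20 kb would lower the share at 10 to 20 kb in both deletion files of each protein, and this held for 1 of 3 proteins, which leaves it open too, as the Mot1 deletion files had 5.00% and 13.6%. A dependence of Arp5, Mot1 and Nc2b on silent chromatin near telomeres is a hypothesis these values leave open, since the lists record only enriched positions and a change of background would act in the same way.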
